A study of Drosophila melanogaster with 3 samples.

How the data were processed

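Transcription factor ChIP-seq was carried out on whole Drosophila melanogaster embryos of 0 to 24 h that express YL-1 fused to GFP, with an antibody against GFP. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels give 3 biological replicates of 1 group and no control group. Control libraries were not analysed here.

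The deposited files were region lists in narrowPeak format, each made in the dm6 and in the dm3 build, per the labels and the inventory beside each sample. A list of peaks and background regions was made for each replicate and for the 3 libraries pooled, against a control library set. A thresholded list was derived from these with the irreproducible discovery rate (IDR). The replicate and pooled lists held 30000 regions each, except that of replicate 1 in dm3 with 29530. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each region is the authors' own, as deposited, and its scale differs between libraries. It was used to rank, describe and filter regions within a list. The authors also give the −log10 of a q-value for each region, which stops at a maximum per list. In the dm6 IDR list it was 4.13 for every peak. The deposited summit offset, in bp from the region start, gave the summit positions. It was the middle of the region, within 1 bp, for 70.0% of IDR peaks and for 97.3% to 98.8% of replicate regions in dm6. No list gives read counts, so the depth is unknown and the statistical intervals cover the counting of peaks or genes. The lists have a set length and reach into background, so replicates were compared by an equal number of top regions.

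Genes and start sites came from the Ensembl 115 annotation of the Release 6 assembly and sequence from the RefSeq copy of that assembly. Analyses used the X, 2L, 2R, 3L, 3R and 4 arms, which hold all dm6 regions. Positions are 1-based in dm6. The strongest 5986 regions of each replicate, as many as the IDR list holds, were called top regions. Overlap meant at least 1 bp, and the share was averaged over both directions of each pair. Chance overlap came from 100 shuffles within the arm. A summit was given the first class that applied among promoter (within 250 bp of a protein-coding TSS), 5' UTR, 3' UTR, coding exon, intron and intergenic. A gene was bound if a summit lay within 250 bp of any annotated TSS. The 34 gene lists, 11 motifs, the rule for named genes and all but 3 of the other settings tried were fixed before the data were examined. Of 262 symbols written out in the lists, 11 had no match by name and were not used here. Lists made by a name pattern hold some genes of other function, which were kept. Lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, or against all other annotated genes for non-coding classes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 odds ratios have 0.5 added to each cell. Genes are not replicates, so these tests describe the lists of this experiment. The replicates give a mean and SD from their top regions. Motifs were sought as consensus matches from the TSS nearest a summit for bound genes and the most upstream TSS for other genes. Signal was compared with a two-sided permutation test with 100000 resamples, and medians had 2000 bootstrap resamples. GC strata were 10 equal groups by GC content within 250 bp of the TSS, pooled by the Mantel-Haenszel test.

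By that rule, the text names the nearest gene of the 10 strongest peaks, the 3 strongest bound members of each list past the threshold, every member of the Domino/Tip60 list, and YL-1. Vmat, Cyp40, the Mst57D genes, neighbours within the same window and the non-coding gene at the peak at rank 4 were named after their values were seen, as were genes in the closing section.

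The steps were tested on simulated data with known answers. Of 3000 genes given a summit near the TSS, 3000 were called bound. For the gene lists, 10 of 10 enriched lists and 0 of 190 random lists were called among 13945 genes. With binding set by GC content alone, the Mantel-Haenszel test called 7 of 100 lists and Fisher's test 100. All 701 planted motif sites were found. A planted summit offset of 20 bp was recovered as 20 bp. The overlap code gave the same answer as bedtools 2.31.1 for 1600 of 1600 queries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

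The other settings tried were other overlap rules, numbers of top regions and ranking columns, promoter windows of 100, 500 and 1000 bp, peaks above the median signal, regions shared by all 3 replicates, each replicate left out, other backgrounds, GC strata and the dm3 lists. For bound genes, arms and lists, leaving a replicate out also replaced the IDR list by the top regions shared by the remaining replicates. The 3 further ones, counting overlapping peaks once, giving each peak to its nearest TSS and leaving members of other function out of 4 lists, were chosen after seeing the data.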

Results

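Chromatin immunoprecipitation followed by sequencing was used to map YL-1 on the genome of Drosophila melanogaster embryos. YL-1 is a subunit of the Domino/Tip60 chromatin complexes, which exchange histone H2A for the variant H2Av and acetylate histones. The embryos were whole animals of both sexes, collected 0 to 24 h after laying, from a transgenic line in which GFP is fused to the carboxy terminus of YL-1. The protein was precipitated with an antibody against GFP. The series held 1 group of 3 biological replicates, so no comparison between groups was made. The measurements were lists of enriched regions, each with a signal value set by the authors' processing. The files give no read totals, so the depth behind each library is unknown. The questions addressed were how well the replicates agreed on their regions, and which parts of the genome and which genes the regions marked.

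The list that passed the authors' reproducibility threshold (irreproducible discovery rate, IDR) held 5986 peaks in the dm6 build. They fell into 4994 separate intervals once overlapping peaks were joined, and covered 2332871 bp, or 1.74% of the X, 2L, 2R, 3L, 3R and 4 arms. These 5986 peaks were the 5986 strongest regions of the list called on the pooled libraries. The 5986 strongest regions of each replicate overlapped by 80.8% ± 0.698 (SD, 3 pairs of replicates), with pair values of 80.1%, 80.8% and 81.5%. Regions placed at random within their arm overlapped by 4.19% on average and by 4.88% at most in 100 shuffles. Across peaks found in both replicates of a pair, the signal correlated with a Spearman coefficient of 0.663 ± 0.00546 (SD, 3 pairs). That correlation is across peaks, which are not independent replicates. Of the IDR peaks, 4311 (72.02%) overlapped a top region in all 3 replicates, 1235 in 2, 427 in 1 and 13 in 0.

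YL-1 peaks lay mainly at the start sites of protein-coding genes. The summit was within 250 bp of an annotated protein-coding transcription start site (TSS) for 4371 of 5986 peaks, or 73.0% (exact binomial 95% interval 71.9% to 74.1%). Such promoter windows make up 6.26% of the bases of the arms, so the share of summits was 11.7-fold higher. In the top regions of the replicates, the promoter share was 71.1% ± 1.25 (SD, n = 3). Introns held 16.8% of summits against 40.9% of bases, and intergenic sequence held 6.80% against 31.1%. Summits were least frequent relative to bases in coding exons, with 0.685% of summits against 14.98% of bases. The 3' UTRs held 28 summits and the 5' UTRs outside promoter windows held 135. The intervals cover the counting of peaks only.

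**Figure D1:**
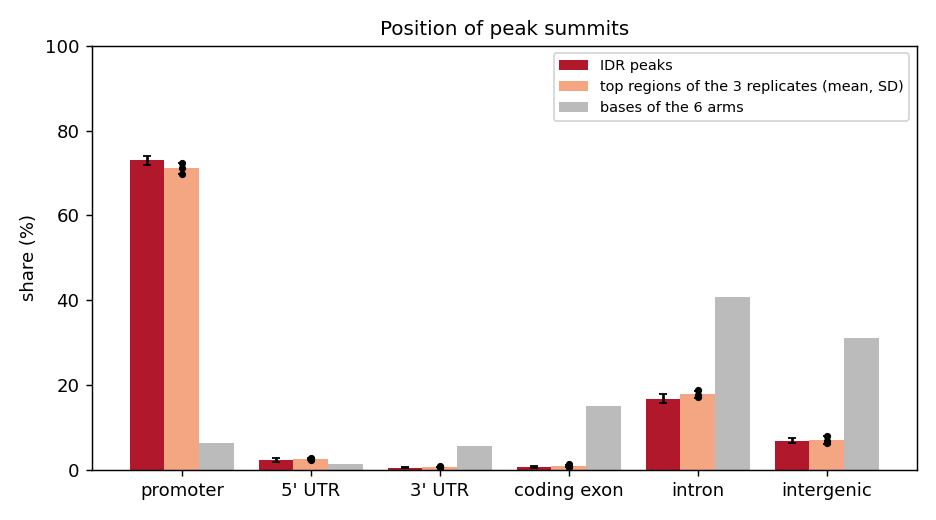
Share of summits, in percent, by annotation class (promoter, 5' UTR, 3' UTR, coding exon, intron, intergenic) for the 5986 IDR peaks (red, exact binomial 95% intervals), for the top regions of the 3 replicates (orange bars with the mean and SD, black points for single replicates), and for the bases of the 6 arms (grey). Promoters held 73.0% of summits and 6.26% of bases.

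Peaks at promoters were also stronger than the others. The median signal was 229.9 at promoter peaks and 189.2 at the other peaks, a ratio of 1.22, and the ratio in the replicates was 1.22 ± 0.0159 (SD, n = 3). The difference of 40.7 had p = 1e-05 in a two-sided permutation test, the smallest p that 100000 resamples can give. The promoter share rose from 57.9% in the weakest decile of peaks to 82.4% in the ninth and was 79.3% in the strongest.

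The 10 strongest peaks (dm6) lay at 6 promoters and at 4 sites farther from a protein-coding TSS. The highest signal, 1369.08, was 6.26 times the median of all IDR peaks. That peak lay on 2L from 6612487 to 6612925, in an intron, 1027 bp downstream of the nearest TSS, that of CG11050. The peak at rank 2 lay on 3L from 19590435 to 19590824, 110 bp from the TSS of CG14100. The peak at rank 3 lay on X from 2703682 to 2704082, 43 bp from the TSS of Ugalt, which encodes a UDP-galactose transporter. The peak at rank 4 lay on 2L from 14023896 to 14024328. It was 2911 bp from the nearest protein-coding TSS, that of hll, and 9 bp from the TSS of the non-coding gene lncRNA:CR31840. The peak at rank 5 lay on 2R from 18336891 to 18337355 in an intron, 20120 bp downstream of the nearest TSS, that of scribbler (sbb). The peak at rank 6 lay on 2L from 480867 to 481297, in an intron and 1396 bp from the nearest TSS, that of cabut (cbt). The peak at rank 7 lay on 2L from 10200836 to 10201310, 44 bp from the TSS of RpL7, a large-subunit ribosomal protein, with Ripalpha also in the window. Rank 8 was the promoter of plexus (px) on 2R, 22514121 to 22514473. Rank 9 was that of CycT on 3L, 17557238 to 17557955, the cyclin of the elongation factor P-TEFb. Rank 10 lay on 3L from 8600749 to 8601192, 3 bp from the TSS of RpL14 and also in the window of Nelf-E, a subunit of the negative elongation factor. In the full replicate lists these peaks ranked between 1 and 43.

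An IDR summit lay within 250 bp of a TSS of 4655 of 13945 protein-coding genes, or 33.4% (exact binomial 95% interval 32.6% to 34.2%). These are called bound genes from here on. The share in the replicates was 32.1% ± 0.750 (SD, n = 3), and 3320 genes were bound in the IDR list and in the top regions of each replicate. Of the promoter peaks, 3220 lay at 1 gene and 1151 at 2 or more. By Fisher's exact test, adjusted over 6 arms, 3R was higher (35.4%, adjusted p = 0.0255), chromosome 4 was higher (37 of 80 genes, 46.3%, adjusted p = 0.0343), X was lower (31.1%, adjusted p = 0.0343) and 2L was lower (31.5%, adjusted p = 0.0376). 2R (33.9%) and 3L (33.5%) did not pass. None of the 4 calls held under every alternative. The log2 odds ratio of chromosome 4 was 0.79, against -0.39 with a 100 bp window (adjusted p = 0.427, exact test). Leaving out a replicate also replaced the IDR list by the top regions shared by the remaining replicates. There the ratio was 0.46 to 0.67 and the call was lost. It was lost as well with regions shared by all 3 replicates (0.43, adjusted p = 0.297, exact test). The log2 odds ratio of X was -0.18, against -0.33 to -0.35 when a replicate was left out and -0.41 for regions shared by all 3. With peaks above the median signal it was -0.62 (adjusted p = 1.09e-11, exact test). The median signal was 199 on X and 220 to 227 on 2L, 2R, 3L and 3R, so that cut removes a larger part of X peaks. No adjustment was made for X copy number in embryos of both sexes. With a 500 bp window the ratio was -0.09 and the call was lost (adjusted p = 0.318, exact test). The 2L call was lost in the regions shared without replicate 2 or 3 (adjusted p = 0.197 and 0.0568, exact test), with log2 odds ratios of -0.12 and -0.16 against -0.15. It was also lost with regions shared by all 3 replicates (-0.14, adjusted p = 0.101, exact test).

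The genes of the Domino/Tip60 complexes themselves were among those bound by YL-1. Of 19 listed members, 16 (84.2%) were bound against 33.3% of the other genes (adjusted p = 1.39e-05, Fisher's exact test, adjusted over 34 lists), and the replicate share was 78.9% ± 5.26 (SD, n = 3). The strongest of these peaks stood at YL-1, the tagged gene (FBgn0032321, 2L, 10970443 to 10972093, plus strand). Its summit at 10970437 was 6 bp from the TSS, its signal of 637 ranked 111 of all peaks and was 2.92 times the median, and it was bound in all 3 replicates. Whether the transgene adds copies of this sequence was not examined, so part of the YL-1 signal could come from them. MrgBP (signal 464, rank 350) and E(Pc), Enhancer of Polycomb (signal 445, rank 411), followed. The acetyltransferase gene Tip60, the ATPase genes pont and rept, the variant histone gene His2Av, and Brd8, Bap55, Eaf6, Gas41, DMAP1, Ing3, MRG15, Nipped-A and Act5C were bound too. Among these, Gas41, DMAP1, Ing3, MRG15 and Nipped-A were bound in 2 replicates. Some peaks were weak, with rept at rank 5708 and DMAP1 at rank 5132. Shares of similar size were found for spliceosome genes (83.8%) and cytoplasmic ribosomal protein genes (90.3%). Arp6 was not bound, with its nearest summit 2218 bp away. The ATPase gene dom and Hcf were not bound under the 250 bp rule, with summits at 255 bp and 262 bp from a TSS.

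Genes of protein synthesis were bound at shares well above those of other genes. Of 93 cytoplasmic ribosomal protein genes, 84 were bound (90.3% against 33.0% of other genes, adjusted p = 1.42e-29, Fisher's exact test), with 91.4% ± 1.08 in the replicates (SD, n = 3). The strongest were RpL7, RpL14 and RpL34b, with signals of 1127, 1037 and 974 and summits 44, 3 and 246 bp from the TSS. A summit can count for more than 1 gene, and the lists were not retested with each peak given to its nearest TSS. Of 73 mitochondrial ribosomal protein genes, 57 were bound (78.1%), led by mRpS10, mRpS11 and mRpL41 (signals 970, 876 and 833). Aminoacyl-tRNA synthetase genes, which load tRNAs with amino acids, were bound in 26 of 32 cases (81.3%), led by GlnRS, TrpRS and SerRS. Translation initiation and elongation factor genes were bound in 34 of 51 cases (66.7%), led by eIF3a, eEF1gamma and eIF6 (signals 903, 728 and 724). Their adjusted p values were 2.28e-14, 8.50e-08 and 3.20e-06.

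Genes of protein breakdown and respiration were bound more often than the other genes too. Of 32 proteasome genes, 25 were bound (78.1%, adjusted p = 6.06e-07, Fisher's exact test), led by Rpt5, Prosbeta1 and Rpn2. Of 87 genes for subunits of the respiratory chain and ATP synthase, 58 were bound (66.7%, adjusted p = 9.17e-10 by the same exact test), led by the ATP synthase genes ATPsynF, ATPsynO and ATPsynB with signals of 653, 561 and 553. The replicate shares were 71.9% ± 3.13 and 65.9% ± 4.04 (SD, n = 3).

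Genes of the transcription and splicing machinery showed the same direction. Of 37 spliceosome genes, 31 were bound (83.8%, adjusted p = 1.11e-09, Fisher's exact test), led by the splicing factor B52, Prp3 and SmD3. Of 35 genes for RNA polymerase II and general transcription factors, 28 were bound (adjusted p = 5.07e-08, exact test), led by the TFIID subunit Taf4 (signal 817, rank 41), Polr2F and TfIIA-S. Of 29 Mediator genes, 21 were bound (72.4%, adjusted p = 4.60e-05, exact test), led by CycC, MED10 and MED6. The Mediator call was lost with a 100 bp window (adjusted p = 0.0549, exact test).

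Chromatin regulators and cell cycle genes were bound more often as well. Of 27 Polycomb and trithorax group genes, 21 were bound (77.8%, adjusted p = 5.75e-06, Fisher's exact test), led by brm, the ATPase of the Brahma remodelling complex (signal 855, rank 31), Jarid2 and the histone methyltransferase gene E(z). Of 12 insulator and architectural protein genes, 10 were bound (83.3%, adjusted p = 0.000717, exact test), led by Dref, which encodes the factor that binds the DNA replication-related element, then Chro and Cp190. Their signals were 927, 742 and 555. Of 36 cell cycle and replication genes, 25 were bound (69.4%, adjusted p = 3.34e-05, exact test), led by dup and dpa, which act in replication licensing, and Dp, the partner of E2F. When the other genes were limited to the 8498 with a listed region in any replicate, the Mediator, architectural and cell cycle calls were lost in the exact test (adjusted p = 0.0848, 0.101 and 0.117). The cell cycle call was also lost with peaks above the median signal (adjusted p = 0.114, exact test).

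**Figure D2:**
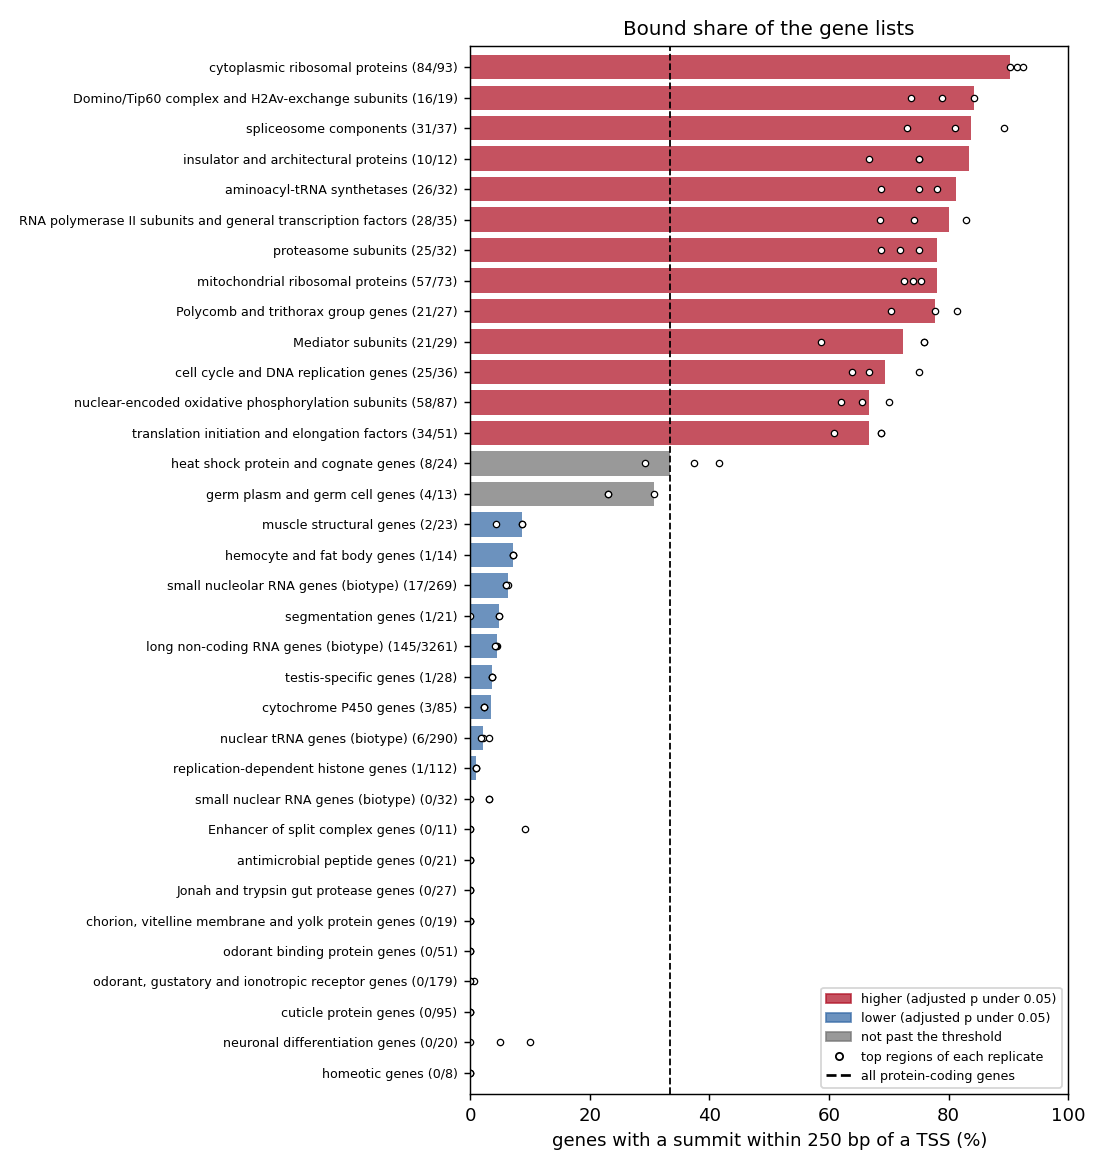
Percent of each gene list with a summit within 250 bp of a TSS, with bound and listed gene numbers in parentheses, where bars give the IDR list (red for a higher and blue for a lower share with adjusted p under 0.05, grey for lists not past that threshold), open points give the top regions of the 3 replicates, and the dashed line marks the 33.4% of all protein-coding genes. Cytoplasmic ribosomal protein genes reach 90.3%, and no chemoreceptor or cuticle gene was bound, while the 1 bound gene of the histone list is His4r.

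Receptor, cuticle, odorant-binding and several other lists were bound less often than the other genes. None of 179 chemoreceptor genes (adjusted p = 4.99e-31, Fisher's exact test), none of 95 cuticle protein genes and none of 51 odorant-binding protein genes had a summit within 250 bp of a TSS. With a count of 0, an approximate upper 95% limit on the share, 3 divided by the number of genes, was 1.68%, 3.16% and 5.88% for these lists. That limit covers counting only and not peaks that were missed. Whole embryos of 0 to 24 h were used, so binding in few cells or for a short time could fall below the threshold. Whether this applies to the lists bound less often was not tested. In the same window, no summit lay at any of 20 neuronal genes, 27 gut protease genes, 21 antimicrobial peptide genes, 19 chorion, vitelline membrane and yolk genes or 11 Enhancer of split complex genes in the IDR list. In the replicates the shares were 5% ± 5 for neuronal, 3.03% ± 5.25 for Enhancer of split and 0.186% ± 0.323 for chemoreceptor genes (SD, n = 3), and 0% in each replicate for the cuticle, odorant-binding, gut protease, antimicrobial and chorion lists. The chorion and yolk list, made by a name pattern, also took in Vmat, a neuronal transporter gene. The bound members of other depleted lists were few. They were Mst85C among 28 genes matched as testis genes, of which Mst57Da, Mst57Db and Mst57Dc are known from the male accessory gland, crq among 14 hemocyte and fat body genes, and Tm1 and Mef2 among 23 muscle genes. Of 85 genes matched as cytochrome P450, 3 were bound, namely Cyp6u1 (in 3 replicates), Cyp1 (in 2) and Cyp317a1 (in 0, with a signal at rank 5848). Cyp1 and the unbound Cyp40 encode cyclophilins, which the name pattern took in, and without them 2 of 83 genes were bound. The adjusted p values of the testis, hemocyte, muscle and P450 lists were 0.000524, 0.0490, 0.0151 and 8.77e-11. In the Mantel-Haenszel test with GC content as strata (n = 13945 genes), the muscle and hemocyte calls were lost (adjusted p = 0.0553 and 0.155), with log2 odds ratios of -2.25 and -2.52 against -2.11 and -2.17 without strata. The chorion and Enhancer of split calls were lost there too (adjusted p = 0.0696 and 0.461, n = 13945 genes), with log2 odds ratios of -1.29 and -1.71 against -4.29 and -3.53, which for lists with 0 bound members rest on the 0.5 added to each cell. The hemocyte call was also lost in the shared regions used when any 1 replicate was left out (adjusted p from 0.140 to 0.141, exact test). It was lost with regions shared by all 3 replicates too (adjusted p = 0.149, exact test), with a log2 odds ratio of -1.63. The muscle call was lost in the regions shared without replicate 1 or 3 (adjusted p = 0.0660 and 0.0662, exact test). With regions shared by all 3 replicates it was lost too (adjusted p = 0.102, exact test, log2 odds ratio -1.56). It was also lost with 100 and 500 bp windows (0.155 and 0.0570). The Enhancer of split call was lost with the same windows (adjusted p = 0.0912 and 0.586, exact test), and with 1000 bp its log2 odds ratio was 0.30. Against the 8498 genes with a listed region, the testis, chorion, Enhancer of split and antimicrobial calls were lost (adjusted p = 0.222 for testis and 0.0593 for the others, exact test). The log2 odds ratio was -1.86 for testis (-3.20 against all genes) and -3.45 for the others (-4.29, -3.53 and -4.43), and the hemocyte list kept 1 member.

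Of 21 segmentation genes, 1 was bound, bcd, at a signal of 147 (rank 5470) and 245 bp from its TSS, in 1 replicate (adjusted p = 0.00499, Fisher's exact test). That call was lost with GC strata (adjusted p = 0.155, Mantel-Haenszel test, n = 13945 genes), where the log2 odds ratio was -2.47 against -2.78 without strata, and against the genes with a listed region (adjusted p = 0.392, Fisher's exact test). None of 8 homeotic genes was bound, and the list did not pass (adjusted p = 0.0622, Fisher's exact test). The same approximate limit was 37.5% here and is rough for so few genes. The homeotic list passed with a 500 bp window (adjusted p = 0.0324, exact test). Germ plasm and germ cell genes (4 of 13) and heat shock genes (8 of 24, 33.3%) did not differ from other genes by the exact test (adjusted p = 1 for both).

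None of 111 replication-dependent histone genes was bound (adjusted p = 2.13e-19, Fisher's exact test). The list as fixed held 112 genes (adjusted p = 6.70e-18, exact test), since its name pattern also took in His4r (3R, 14625755 to 14626614), the replication-independent replacement gene of histone H4. His4r was bound in all 3 replicates, with a signal of 432. For the 111 replication-dependent genes, the median share of 32-base sequences around the TSS that occur once in the genome was 0%. That share was under 20% for 109 of them, and none had a listed region in any replicate or in the pooled list. Their unbound state may therefore be a limit of mapping, and the p-values say little about binding at these genes. Non-coding genes were bound less often than the other annotated genes. Shares were 2.07% of 290 tRNA genes, 0 of 32 snRNA genes, 6.32% of 269 snoRNA genes and 4.45% of 3261 long non-coding RNA genes, against 26.98%, 26.6%, 26.9% and 31.4% of the other annotated genes. The snRNA share in the replicates was 2.08% ± 1.80 (SD, n = 3). The adjusted p values were 1.42e-29, 0.000110, 5.83e-17 and 4.85e-282 by Fisher's exact test. The share of sequences that occur once was not measured for non-coding genes, so limits of mapping were not tested there. The strongest bound tRNA genes were tRNA:Tyr-GTA-1-8, tRNA:His-GTG-1-3 and tRNA:Arg-CCT-1-2, with summits 185, 220 and 233 bp from the TSS. Among snoRNA genes they were snoRNA:Me18S-A1576, snoRNA:Psi18S-920 and snoRNA:Me28S-C3227a, with summits 154, 77 and 223 bp from the annotated 5' end. Whether such ends are starts of transcription, or the summits belong to other genes nearby, was not examined. Among long non-coding RNAs they were lncRNA:CR31840, sisRNA:CR46364 and lncRNA:CR44417, with signals of 1269, 957 and 938. The snoRNA call was lost with a 1000 bp window, where the log2 odds ratio was 0.11. In all, 13 of the 34 lists were bound more often, 18 less often, with the histone list among them, and 3 did not pass.

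Genes with a divergent neighbour, meaning the TSS of another protein-coding gene on the opposite strand within 500 bp upstream, were bound far more often. Of 3687 such genes, 2417 (65.6%) were bound, against 2238 of 10258 others (21.8%). The odds ratio was 6.82 (95% interval 6.28 to 7.41), and the log10 of the one-sided p of Fisher's exact test was -490. In the replicates the shares were 63.1% ± 2.24 and 21.0% ± 0.710 (SD, n = 3). One summit can count for both genes of such a pair. When each peak counted for its nearest TSS only, 45.3% of divergent genes and 21.0% of the others were bound, with a log2 odds ratio of 1.64 in place of 2.77 (p = 2.55e-167, exact test). That alternative was chosen after seeing the data.

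The position of summits was measured at peaks within 250 bp of a TSS, a limit that also bounds the values. At 1916 such peaks near genes without an opposite-strand TSS within 1000 bp, the median summit was 11.5 bp downstream of the TSS (bootstrap 95% interval 5.49 to 17 bp), with quartiles at -49 and 71 bp. The medians of the replicates were 15, 13 and 4 bp, or 10.7 ± 5.86 bp (SD, n = 3). Of these summits, 1047 lay downstream and 864 upstream. With all genes kept, the median was 2 bp. For 70.0% of the IDR peaks the summit was the middle of the region within 1 bp, which limits the precision of single positions.

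**Figure D3:**
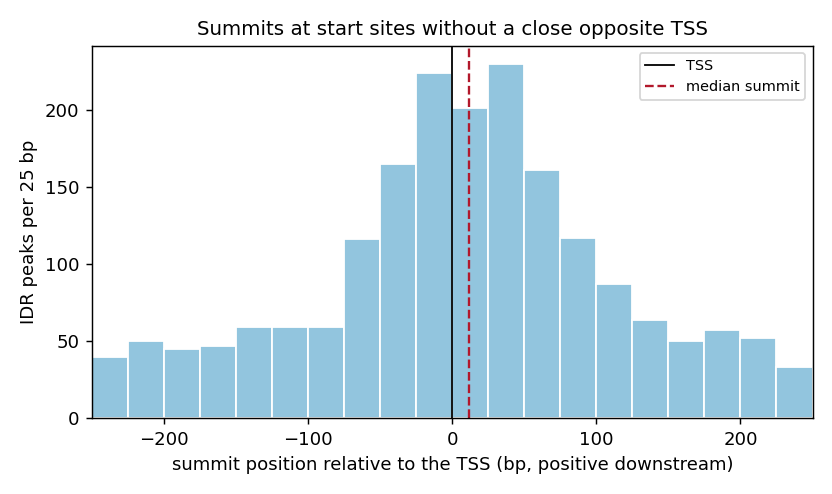
Number of IDR peaks per 25 bp bin by summit position relative to the TSS, in bp with positive values downstream, for 1916 peaks within 250 bp of a TSS of genes without an opposite-strand TSS within 1000 bp. The solid line is the TSS and the dashed line the median at 11.5 bp.

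The promoters of bound genes carried a set of sequence motifs of broadly active genes and seldom a TATA box. Motif 1, the M1BP site, was found at 9.56% of bound and 1.16% of other genes, an 8.22-fold difference. The DNA replication-related element (DRE) was found at 24.8% against 7.40%. Ohler motif 7 was found at 15.7% against 3.69%, Ohler motif 6 at 3.502% against 0.818%, and the E-box core at 21.9% against 10.3%. The TCT initiator, known from ribosomal protein genes, was found at 1.27% against 0.495%, and the Pho site at 10.7% against 8.54%. Less frequent at bound genes were the TATA box (1.10% against 10.1%), the initiator (6.02% against 15.5%), the GAGA element (2.99% against 4.36%) and the Zelda site (0.773% against 1.15%). Each of the 11 motifs passed Fisher's exact test adjusted over the motifs, with adjusted p = 1.09e-168 for the DRE, 5.90e-119 for motif 1, 2.76e-110 for the TATA box and 0.0400 for the Zelda site. The replicate shares at bound genes were 24.8% ± 0.242 for the DRE and 9.42% ± 0.273 for motif 1 (SD, n = 3). The Zelda call was lost in the exact test with peaks above the median signal and with peaks shared by all 3 replicates (adjusted p = 0.120 and 0.182). It was also lost with GC strata (adjusted p = 0.178, Mantel-Haenszel test, n = 13945 genes). The Pho call was lost when every annotated TSS of the genes not bound was searched (adjusted p = 0.463, exact test).

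Within 100 bp of the summits, compared with windows 1000 bp to either side, the DRE was 5.60-fold and motif 1 was 19.2-fold more frequent (13.2% against 2.36% and 5.296% against 0.276%). The GAGA element and the TATA box, which were less frequent at bound promoters, were 1.57-fold and 1.27-fold more frequent at summits (4.54% against 2.90%, adjusted p = 4.53e-08, and 12.2% against 9.56%, adjusted p = 1.69e-07, Fisher's exact test). A match counted there at any position in the window. By class, GAGA stood at 2.97% of promoter summits, close to the flank share, and at 8.79% of the other summits. The TATA box stood at 11.3% and 14.6%. The initiator did not pass in the comparison of summits with flanks (37.9% against 36.7%, adjusted p = 0.132, exact test).

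**Figure D4:**
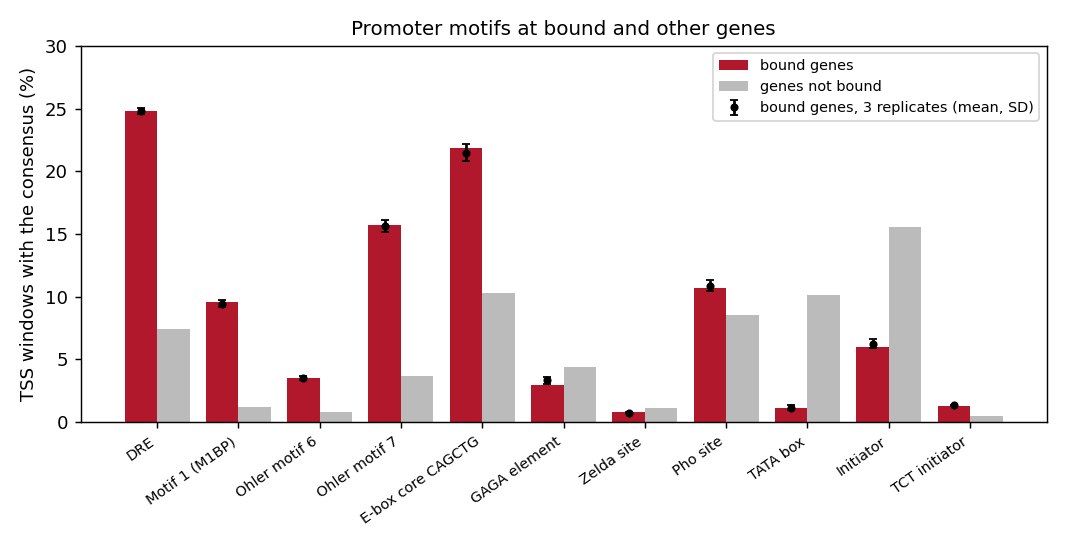
Percent of TSS windows that hold each of 11 consensus motifs for the 4655 bound genes (red) and the 9290 genes not bound (grey), with points and error bars for the mean and SD of the bound genes in the 3 replicates. The DRE stands at 24.8% of bound and 7.40% of other genes, and the TATA box at 1.10% and 10.1%.

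The lists in the older dm3 build were compared in peak number, arm shares and replicate overlap only. The IDR list held 5389 peaks, 0.900 times the number in dm6, and 1 of them lay off the 6 arms. The share of peaks per arm differed by at most 0.551 percentage points between builds. The top regions of the replicates overlapped by 80.7% ± 0.678 (SD, 3 pairs of replicates) in dm3. No coordinates were converted between builds.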

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

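The list of regions called on the pooled libraries held a signal outside the IDR list that the report does not use. In dm6, 5303 pooled regions had a q-value under 0.05 and overlapped no IDR peak. Their median signal was 90.4, and the median of the IDR peaks was 2.42 times as high. Of these regions, 31.6% (1675; exact binomial 95% interval 30.3% to 32.9%) had their summit within 250 bp of a protein-coding TSS, against 73.0% of the IDR peaks. They reached 1376 protein-coding genes that the IDR list did not. A region with a q-value under 0.05 was present in all 3 replicates at 1370 of the 5303 regions (25.8%). No biological explanation was tested.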

How the results depend on the processing

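Counting each group of overlapping peaks once, giving each peak to its nearest TSS and leaving members of other function out of 4 lists were alternatives chosen after seeing the data; the last ended none of those 4 calls. The divergent promoter result and the promoter signal difference kept their direction and side of the threshold under every alternative run. Lists past the threshold numbered 21 to 31, against 31 in the report, and motifs past it 10 against 11. Replicate overlap was 69.9% with 50% reciprocal overlap, 60.9% with summits within 100 bp, 75.7% with 2993 top regions and 76.9% with 2 times as many as in the report. Leaving out a replicate left 1 pair, so the values of 80.1% to 81.5%, and correlations of 0.657 to 0.667, were those of single pairs and no further check. Above the median signal the correlation was 0.569. The share of IDR peaks in all 3 replicates was 95.7% with 2 times as many top regions, 38.7% with 2993, and 48.6% with summits within 100 bp. The promoter share was 50.3%, 81.4% and 86.1% with windows of 100, 500 and 1000 bp, 79.9% above the median signal and 77.0% for regions shared by all 3 replicates. Wider windows hold more bases and stricter sets fewer peaks by construction. Bound genes numbered 4655 in the report, 2915 above the median signal and 3557 in regions shared by all 3 replicates. Leaving out a replicate, which also replaced the IDR list by the top regions shared by the remaining replicates, gave 3851 to 3945. Lists bound less often numbered 11 against genes with a listed region (8498 protein-coding, 9707 in all), which tests fewer genes, and 9 with GC strata, where the 4 non-coding lists were not tested and 5 calls were lost. The median offset was 2 bp with divergent genes kept. Directions turned for chromosome 4 (log2 odds ratio -0.39 with 100 bp and -0.40 above the median signal), for the Enhancer of split and snoRNA lists with 1000 bp (0.30 and 0.11), and for the histone and hemocyte lists against genes with a listed region (1.31 for both), where 1 member of each was left. The cause was not tested for the GC strata, the arms and the wide windows. Across lists, 337 comparisons kept their call, 31 lost it, 2 gained it and 4 turned; across motifs, 40 kept and 4 lost it. The q-value column gave no test of peak signal by class, because all IDR peaks share 1 value. No paired analysis was possible because the series has 1 group. Unknown depth limits what an absent peak can say.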

Other observations

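The choice of the 3 patterns below, the final name rule for duplicates and the choice of the motif tests among peaks found in all 3 replicates were made after seeing the data, as was the test of GC content at distal summits; the bounds of the other tests were set before their results were seen, though the GC test of the duplicates was first run under the earlier name rule. Genes not bound in the IDR list were reached by the weaker pooled regions with q under 0.05 in some groups more than in others. Of 11 cell cycle genes that the IDR list left out, 9 had such a region, namely CycD, CycE, Cdk4, Mcm3, Orc4, PCNA, Rbf, fzr and twe, against 14.7% of the other genes left out (adjusted p = 7.87e-06, Fisher's exact test over 34 lists). Of 16 mitochondrial ribosomal protein genes left out, 9 had one (56.3%, adjusted p = 0.000651, exact test). The other lists bound more often in the IDR list did not pass. Among them were translation factor genes (6 of 17, 35.3%, adjusted p = 0.0729, exact test) and respiratory genes (3 of 29, 10.3%, adjusted p = 0.869, exact test). No cuticle gene of 95 had one, against 14.96% of the others (adjusted p = 3.54e-06, Fisher's exact test), and 2 of 179 chemoreceptor genes did (adjusted p = 3.43e-09, exact test). The homeotic genes (0 of 8, adjusted p = 0.720, exact test) and the neuronal genes (4 of 20, Appl, Syt1, nrv3 and onecut, adjusted p = 0.637) did not pass, against 14.8% of the others for both. Arp6, the Domino/Tip60 member farthest from an IDR summit, had one.

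Of the IDR peaks, 834 lay more than 1000 bp from any protein-coding TSS. Such summits fell inside 413 protein-coding genes, of which 219 (53.0%) were also bound at a TSS. The median length of these genes was 20688 bp, against 2166 bp for all protein-coding genes. Gene length was not adjusted for. Of the gene lists, they held 6 of 27 Polycomb and trithorax group genes (Psc, ph-p, trx, kis, osa and Trl), 3 of 23 muscle genes (Mef2, Msp300 and Prm), the homeotic genes Antp and Abd-B, the patterning genes cad and ptc, the cell cycle genes Cdk4 and E2f1, the translation factor genes eIF4G2 and eIF5B, and RpS26, HisRS, COX7AL2, Hsp83 and fne. Enrichment of the lists among these genes was not tested.

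None of 111 replication-dependent histone genes was bound. Reads shared between the repeat copies are a candidate explanation. Within 250 bp of the TSS of these genes, the median share of 32-base sequences that occur once in the genome was 0%, with a highest value of 36.4%, against 100% for the bound replacement gene His4r and a median of 100% for all protein-coding genes. None of the 111 had a listed region in any replicate or in the pooled list. The unbound state of these genes may therefore be a limit of mapping, though how the authors treated reads with several matches is not given in the sources used here, and no biological explanation was tested.

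In the respiratory and cytoplasmic ribosomal lists, 3 of 21 duplicates were bound, meaning genes whose name without a final L, L and a digit, or -like is another member, against 87.4% of 159 others. Among the respiratory genes, 0 of 17 duplicates and 58 of 70 others (82.9%) were bound. In the ribosomal list, 3 of 4 genes so named were bound, RpL7-like, RpL24-like and RpLP0-like. The rule goes by name only, and whether these genes are copies was not examined. It leaves out names with other endings, such as the unbound RpL10Aa, RpL37-2, RpS5b, RpS10a, RpS15Ab and RpS19b and the bound RpL34b. The unbound COX6AL, COX6AL2, COX6CL and ATPsynepsilonL were also counted among the others. The 2 lists can therefore not be contrasted by this rule. Shared reads are argued against, since the median unique share at the 18 unbound duplicates was 100% and the lowest was 100%. Low GC content is argued against too, since the median around the TSS was 39.9% for the duplicates and 38.5% for the other members. The log2 odds ratio over GC strata was -5.47 (-5.17 without strata, and -4.12 without strata under the name rule used first, which also took in genes such as RpL3 and ND-MNLL). Restricted expression of such duplicates is a candidate explanation that these files cannot test, and no biological explanation was tested.

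The 1615 peaks away from start sites differed in motifs from promoter peaks. Within 100 bp of the summit the DRE was found at 2.72% of distal and 17.1% of promoter peaks, and motif 1 at 0.310% and 7.14%. The GAGA element was found at 8.79% and 2.97% (adjusted p = 5.88e-19, Fisher's exact test). In windows 1000 bp to either side of the IDR summits, the shares were 2.36%, 0.276% and 2.90%. The distal DRE and motif 1 shares were thus near the flank shares, while the distal GAGA share was higher. The classes were set by distance to a TSS, and unbound sites were not compared here. Whether the difference exceeds that between promoters and other sequence was therefore not tested. Of the distal peaks, 781 lay within 1000 bp of a protein-coding TSS. In the replicates, the GAGA share was 9.21% ± 1.25 at distal and 3.36% ± 0.674 at promoter regions (SD, n = 3); 80 distal peaks (4.95%) lay near a non-coding TSS, and start sites missing from the annotation were not tested for. The median GC content within 250 bp was 40.9% at both and differed by 0 percentage points (bootstrap 95% interval -0.205 to 0.399). The bound for that comparison was set after the medians were seen. Over GC strata of the summits, the log2 odds ratio of promoter against distal peaks was 2.88 for the DRE and -1.68 for GAGA. Without strata, that of distal against promoter peaks was -2.86 and 1.65. Lower GC content around distal summits is therefore argued against for these motifs. Chance regions near the threshold are argued against as the whole cause, since among the 920 distal and 3391 promoter peaks found in all 3 replicates the log2 odds ratio was 2.54 for the DRE at promoter against distal peaks (bootstrap 95% interval 2.07 to 3.11) and 1.89 for GAGA at distal against promoter peaks (1.43 to 2.33). Whether distal peaks hold more such regions stays open, since 57.0% of them and 77.6% of promoter peaks were found in all 3 replicates, a difference of 10.4 percentage points at equal signal (95% interval 8.02 to 12.8), between the bounds of 10 and 20 set beforehand, and no biological explanation was tested.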
